A study of Rattus norvegicus with 8 samples.

How the data were processed

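Dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, were taken from Sprague Dawley rats 7 days after spinal nerve ligation or a sham operation, per the labels' protocols. Spinal nerve ligation is the Chung model of neuropathic pain, in which spinal nerves are tied close to the ganglion. Each of the 2 groups held 4 samples, which the labels call biological replicates, and each sample was pooled from 2 animals. The labels name the control samples as contralateral in their titles and as sham-operated in their descriptions, and the ligation samples as ipsilateral. The side of the body and the operation therefore could not be told apart in any comparison.

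Per the labels' protocols, 100 ng of total RNA was amplified in 2 rounds of reverse transcription and in vitro transcription. On each of the 8 arrays the sample was labelled with Cy5 and hybridised against 1 common reference, a control pool labelled with Cy3, with no dye swap. The arrays were quantified with Agilent Feature Extraction 8.5.1.1, per the submitters' processing notes. The background correction, the dye and array normalization and the program that wrote the table are not given in the sources used here.

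The deposited table gave, per the file headers, an intensity for each of the 2 channels on a relative linear scale. The authors' p-value for the ratio of the 2 channels within each array stood beside them. A separate deposited table held log10 values, which equalled the log10 of sample over reference intensity to within 0.005 for 100% of the spots and had a median of 0 on every array. It was a rounded copy, so it was not run as an alternative. The authors' p-values were not used in any comparison. All columns of values were matched to a sample by name, and 0 were left unmapped.

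Intensities were printed with 2 decimals, and with 3 digits below 0.01. The median intensity was 0.17 to 0.22 in the sample channel, so ratios of dim probes moved in coarse steps. A ratio of exactly 1 was found for 35.9% to 38.7% of spots on the control arrays and 17.0% to 19.1% on the ligation arrays. At the bright end, 12 of the 16 channels had at least 20 spots within 0.05 of a single intensity, which lay between 17.77 and 30.09. The table carried no flag for saturated spots. A fold change of a gene whose brighter group lay in that range could be understated, and this is said beside each such gene. The number of arrays limits the precision of each value. The fitted log2 fold changes had a median standard error of 0.063 over all probes, and 0.122 in the dimmest 25% of probes against 0.049 in the brightest 25%.

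Log2 ratios of sample over reference were computed from the intensities without further scaling, since their median was 0 on every array. The table held 23557 spots of 22491 different probes, and spots of 1 probe were averaged. Of the probes, 22379 had a value on at least 2 arrays of each group and were tested, and 112 were left out. Of the spots, 354 had no value on at least 1 array. Their median sample intensity was above 10 in 44.1%, against 2.1% of the other spots, so blanks were more frequent among bright spots. Probes were named through a table of rat genes of the GRCr8 assembly, 2954 by accession, 10335 by symbol and 1898 by a single synonym. A further 321 kept the name of the file and 6983 had no gene name. No coordinates are given, because no genome build is named for the array. A gene took the value of its probe with the highest mean intensity, which gave 10746 genes with a value. Of 3369 genes with several probes, 1769 had at least 2 probes past the test, and 211 of these had them in both directions.

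Ligation was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with the Benjamini-Hochberg adjusted p under 0.05 as the threshold over all probes. A count with a fold of at least 2 was made from the same fit. The mean of the control arrays was tested against the reference in that fit too, as background. Of 30 gene lists, the 28 with at least 5 measured members were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Table handling and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

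The lists, the designs and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls among genes past the test whose 4 ligation arrays lay apart from the 4 control arrays, leaving out placeholder symbols. From each list it took the 3 members with the smallest adjusted p and the 1 with the smallest change. It also took Atf3, Gal, Npy, Vip, Cacna2d1, Scn9a, Scn10a, Scn11a, Trpv1, P2rx3, Tac1, Calca, Oprm1, Gap43 and Sprr1a. Vip was not matched among the named probes and is not analysed here. The rule took 137 genes, and the report prints values for 97 of them, picked for the cell type or function they stand for, after it had been seen which genes had 1 array far from the others. Values of 15 further genes, most of them list members that moved against their list, were chosen after they were seen.

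The fit was tested on simulated arrays for the comparison of ligation with control, with 22158 probes, in 10 draws of 200 changed probes each. With values rounded as in the table, 61.6% of probes changed by 0.5 on the log2 scale were recovered, 87.8% of those changed by 1, 98.0% of those changed by 2 and 99.8% of those changed by 3. Of the calls, 12.8% were unchanged probes, against 4.9% when the simulated values were not rounded. In a simulation with few changed probes, rounding thus raised false calls above the nominal 5%. For the set test, 10 of 10 simulated lists of 20 genes shifted by 0.5 were recovered and 1 of 10 unshifted lists was called, over 10661 genes in a single draw. The simulated genes varied independently of one another, so this does not test lists whose genes vary together. In the data the estimated correlation reached 0.641, for fibroblast and matrix genes.

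Alternatives chosen before the data were examined were quantile normalization between arrays, median centring, probes above the median of mean intensity, array weights, each array left out in turn, a replicate block, eBayes with trend and robust, the sample channel alone, Welch's test, genes as the unit, the mean over the probes of a gene, camera with an estimated correlation and fry. Random noise within the rounding step and a fit on ligation arrays 1 and 4 alone were added after seeing the data. So was a second list of 36 muscle genes, for the reference, of which 20 were measured and values of 6 had been seen when it was written.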

Results

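Gene expression was measured in dorsal root ganglia of Sprague Dawley rats 7 days after spinal nerve ligation, with 4 ligation and 4 control samples, each hybridised on 1 two-colour array against a common pooled reference. Dorsal root ganglia hold the cell bodies of sensory neurons together with satellite glia, Schwann cells, fibroblasts, vessels and immune cells. Values are log2 ratios of sample over reference, and a fold change is the difference between the mean ratios of the 2 groups. The median sample intensity was 0.17 to 0.20 on the control arrays and 0.21 to 0.22 on the ligation arrays, on a scale that reached 26.29 to 32.26. The standard deviation of the log2 ratios over spots was 0.184 to 0.226 on the control arrays and 0.589 to 0.632 on the ligation arrays. Of the probes, 13105 of 22379 (58.6%) passed the test between ligation and control, 5897 higher and 7208 lower. At least a 2-fold difference was found for 1809 probes, 1046 higher and 763 lower. Under quantile normalization between arrays 6365 probes passed, 1012 of them with at least a 2-fold difference. That setting gives all arrays 1 spread of ratios, so it enlarges the small ratios of the control arrays. Calls lost or turned under it can come from this, which was not tested apart. Among 10746 genes with 1 probe each, 3296 rose and 3911 fell. The share of probes past the test was 25.9% in the dimmest 25% of probes and 76.9% in the brightest 25%.

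The comparison of ligation with control asked which genes went up and which went down in the ligated ganglia. Csrp3 (muscle LIM protein, NM_057144 in the table) rose most, 325-fold (log2 8.34 ± 0.26, SE, n = 4 per group, adjusted p = 5.63e-07). Atf3, a stress transcription factor known as a marker of axotomised neurons (NM_012912), rose from a mean log2 ratio of -0.85 ± 0.18 (SD) in control to 4.15 ± 0.19 in ligation (adjusted p = 2.85e-07). The other genes among the 10 largest rises were Cldn4 (tight junction protein, 79.4-fold), Serpina3n (protease inhibitor, 49.7-fold), Il24 (cytokine, 33.2-fold), Ankrd1 (30.9-fold), Tgm1 (transglutaminase, log2 change 4.64), Arg1 (arginase, 20.8-fold), Npy (neuropeptide Y, 20.5-fold) and Fcrl2 (18.6-fold, named Fcrls in the table). Iapp, the peptide amylin (NM_012586), fell most, 23.1-fold (-4.53 ± 0.49, adjusted p = 1.39e-04), and Sst, somatostatin (NM_012659), fell 19.8-fold (-4.31 ± 0.63, adjusted p = 7.3e-04). The other large falls were in Chrna3 (nicotinic receptor subunit, 14.9-fold), Cdh3 (P-cadherin, 14.7-fold), Scn11a (sodium channel Nav1.9, 14.6-fold), Slc16a12 (13.5-fold), Nptx1 (neuronal pentraxin, 12.3-fold), Htr3a (serotonin-gated channel subunit, 11.9-fold), Grik1 (kainate receptor subunit, log2 change -3.46) and Nrn1 (neuritin, 9.80-fold). By the naming rule, the 4 ligation arrays lay apart from the 4 control arrays for all 20 genes. Ankrd1 and Cdh3 each had 2 probes, of which 1 passed the test. Csrp3, Cldn4, Serpina3n, Il24 and Tgm1 were dim in control, and rounding alone allowed log2 changes of 8.10 to 8.64, 5.81 to 6.89, 4.83 to 6.68, 4.03 to 6.45 and 4.17 to 5.16. It allowed 4.79 to 5.11 for Ankrd1 and 4.18 to 4.53 for Npy, also dim in control, and -4.79 to -4.31 for Iapp and -3.78 to -3.39 for Htr3a, dim in ligation. The bounds of Sst were -4.34 to -4.28 and overlapped those of Iapp, so the order of these falls is not settled.

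**Figure D1:**
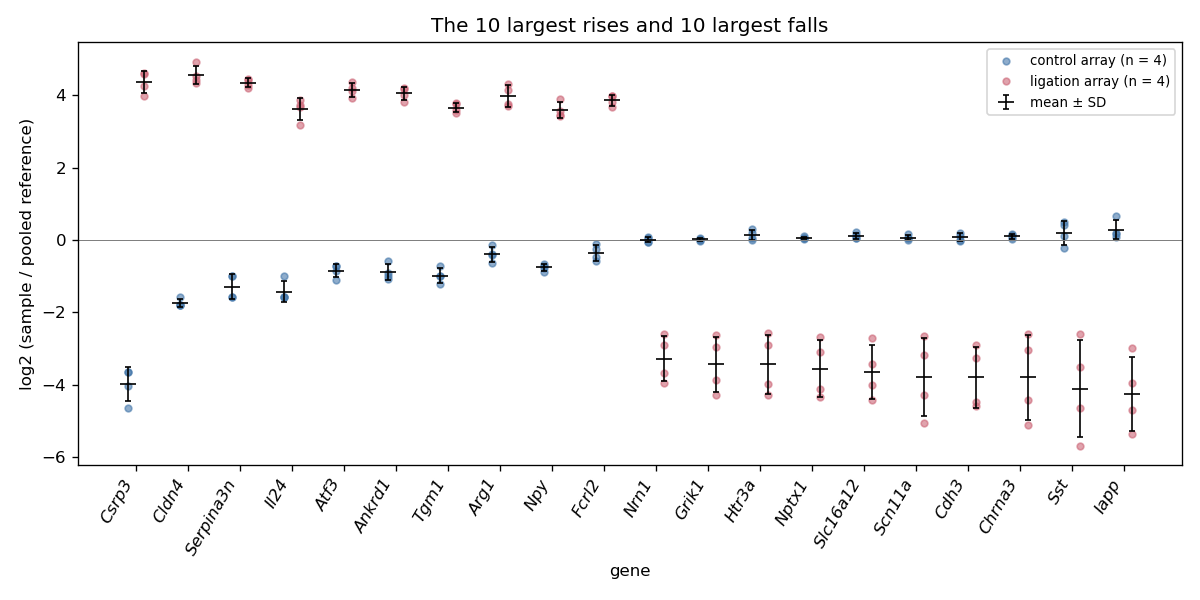
Log2 ratio of sample over pooled reference (vertical axis) for the 10 genes with the largest rise and the 10 with the largest fall (horizontal axis), with 1 point per array, n = 4 per group, and the mean with its SD in black. The ligation arrays lie above the control arrays for the genes from Csrp3 to Fcrl2 and below them for the genes from Nrn1 to Iapp, where the SD within ligation reached 1.34 for Sst.

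Genes of the injury and regeneration list rose together, 22 of 23 measured members passing the test as higher and 0 as lower. Besides Csrp3, Atf3, Ankrd1 and Arg1, Gadd45a, a growth arrest and DNA damage gene, rose 7.17-fold, and Gap43 of the growth cone rose 2.23-fold. Sprr1a, deposited under the name Sprr1al, rose 1.88-fold (rounding bounds 0.58 to 1.24 on the log2 scale), while Stat3 rose 1.15-fold. The list passed the set test (adjusted p = 4.35e-09) but not with an estimated correlation (adjusted p = 0.128). Of the 5 measured neuropeptides reported as induced by axotomy, 4 rose: Npy, Gal (galanin, 7.86-fold), Adcyap1 (PACAP, 2.06-fold) and Cck (cholecystokinin, 1.57-fold). Crh, corticotropin-releasing hormone, fell by 2.18 on the log2 scale (adjusted p = 7.07e-04). This list had an adjusted p of 0.0379, or 0.268 with an estimated correlation, and it did not pass without ligation replicate 3 or without ligation replicate 4. Nor did it pass with the replicate block (adjusted p = 0.0625 in the set test). Gap43, Gal and Adcyap1 lay in ligation in the intensity range where bright spots piled up, so their folds may be understated, and Stat3 did not pass under quantile normalization between arrays.

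Most nociceptor genes, which mark the small sensory neurons that detect painful stimuli, fell, 14 of 16 measured members passing as lower and 1 as higher. Examples were Trpv1, the capsaicin receptor, which fell 6.67-fold (-2.74 ± 0.25), Scn10a (sodium channel Nav1.8, 5.48-fold), Tac1 (substance P, 2.84-fold) and P2rx3 (ATP-gated channel, 1.90-fold). Calca did not pass (log2 -0.02, adjusted p = 0.882), on a probe with an intensity of 0.055 in control. Gfra3, a receptor of artemin, rose 1.41-fold. The median log2 change of the nociceptor list was -1.58, with an adjusted p of 6.57e-04 in the set test, or 0.233 with an estimated correlation. Large and mechanosensory neuron genes fell in 9 of 12 members, with Kcnc1 (6.12-fold), Scn1a (5.78-fold) and the neurofilament gene Nefh (2.92-fold) as examples, and the list passed the set test (adjusted p = 4.38e-04), but not with an estimated correlation (adjusted p = 0.128). General neuronal genes fell in 10 of 11 members, among them Syt1 (synaptotagmin, 3.05-fold), Isl1 (2.43-fold) and Syp (synaptophysin, 2.06-fold), while Tubb3 did not pass (log2 0.01, adjusted p = 0.927), except on ligation arrays 1 and 4 alone. This list had an adjusted p of 0.00187, or 0.268 with an estimated correlation. The falls were not equally deep on all ligation arrays: the median log2 ratio of the 19 genes that fell at least 8-fold was -3.81 and -3.98 on ligation arrays 1 and 4, and -2.98 and -2.67 on arrays 2 and 3. The median of the nociceptor list was -1.63, -1.23, -1.15 and -1.90 on ligation arrays 1 to 4, and that of the large neuron list was -1.23, -1.25, -1.25 and -1.04. Tac1 and P2rx3 lay in the piled-up intensity range in control, so their falls may be understated, and Gfra3 did not pass under quantile normalization between arrays.

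**Figure D2:**
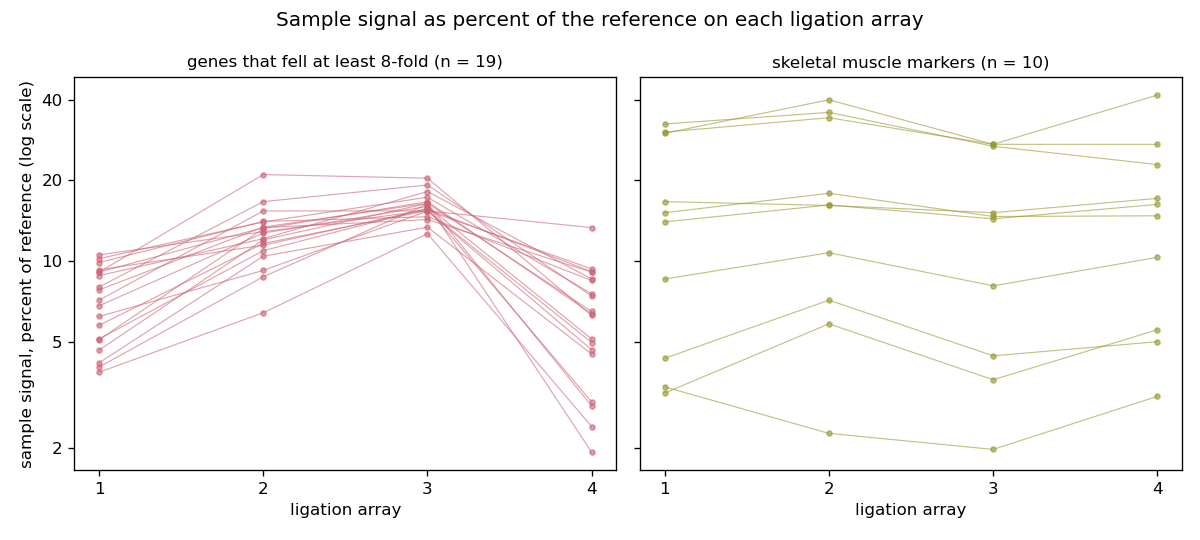
Sample signal in percent of the reference signal (vertical axis, log scale) on ligation arrays 1 to 4 (horizontal axis), for the 19 genes that fell at least 8-fold (left) and for the 10 skeletal muscle markers (right), with 1 point per gene and array and thin lines joining the points of 1 gene. On the left the signal is higher on arrays 2 and 3 than on arrays 1 and 4, with Sst at 8.74% and 16.3% against 4.02% and 1.93%, and on the right Myh1 lies between 3.22% and 5.83%.

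Potassium channel genes fell in 25 of 33 measured members, with a median log2 change of -1.23. Kcnab2, an accessory subunit, fell 3.91-fold (-1.97 ± 0.03, adjusted p = 6.92e-08), and Kcnc1 fell as above. Kcnmb4, a subunit of the large-conductance calcium-activated channel, rose 2.06-fold and Kcnn1 rose 1.19-fold. The potassium channel list passed the set test (adjusted p = 2.61e-06), and it was the 1 list that also passed with an estimated correlation (adjusted p = 0.0422). Voltage-gated sodium channel genes fell in 8 of 12 members, with Scn1a, Scn10a, Scn11a, Scn8a (3.26-fold) and Scn9a (Nav1.7, 2.46-fold) among them, whereas Scn3a (Nav1.3) rose 2.26-fold. Their adjusted p was 0.0195, or 0.128 with an estimated correlation, and the list did not pass when only probes above the median intensity were kept. Voltage-gated calcium channel genes fell in 7 of 13 members, with Cacng2 (2.92-fold, rounding bounds -2.03 to -1.09 on the log2 scale) and Cacnb3 (2.11-fold) as examples, while Cacna2d1, the subunit bound by gabapentin, rose 4.54-fold (2.18 ± 0.14). The calcium channel list did not pass (adjusted p = 0.271). Kcnn1 did not pass when any of 5 single arrays was left out, under quantile normalization between arrays or with the probes of a gene averaged.

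In the list of opioid, cannabinoid, adrenergic and GABA receptors, which also holds muscarinic and serotonin receptors, 12 of 19 genes were lower and 2 higher. Htr3b (5.82-fold) and Htr3a fell, as did the GABA-B receptor gene Gabbr2 (3.49-fold) and the mu opioid receptor gene Oprm1 (2.62-fold). Gabra5 (2.99-fold) and Gabrb1 (2.42-fold), subunits of the GABA-A receptor, rose. The list had an adjusted p of 0.0148, or 0.128 with an estimated correlation. Ionotropic glutamate receptor genes fell in 6 of 11 members, with Grik1 and Gria2 (5.19-fold) as examples, while Grik2 (2.22-fold) and Grin2b (1.16-fold) rose, and that list did not pass (adjusted p = 0.0821). Oprm1 was dim, and rounding alone allowed log2 changes of -2.30 to -0.56. Gabrb1, Grik2 and Grin2b did not pass under quantile normalization between arrays. Nor did Grin2b when any of 7 single arrays was left out, with the replicate block, with trend and robust, with rounding noise or on ligation arrays 1 and 4 alone.

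Most lists of immune genes rose. Macrophage markers were higher in 18 of 21 members and lower in 0, with Trem2 (10.1-fold), the protease Ctss (8.63-fold) and the complement gene C1qb (6.38-fold) as examples, and the median log2 change was 1.95. The macrophage list had an adjusted p of 4.35e-09, or 0.128 with an estimated correlation. All 8 measured MHC class II genes, which present antigen, rose, with Cd74 at 10.6-fold (3.41 ± 0.09), RT1-Da at 8.87-fold and RT1-DMb at 4.54-fold (adjusted p = 2.89e-05 in the set test). With an estimated correlation the MHC class II list had an adjusted p of 0.128. Complement genes rose in 11 of 14 members, among them C2 (4.99-fold), the anaphylatoxin receptor gene C5ar1 (4.16-fold) and C4b (3.71-fold), whereas Cd55, an inhibitor of complement, fell 6.83-fold. The complement list had an adjusted p of 3.05e-04, or 0.128 with an estimated correlation. Cytokine and chemokine genes rose in 16 of 24 members, with Csf1 (6.06-fold), Il18 (5.78-fold) and Cxcl9 (5.66-fold) as examples, and Cx3cl1 (fractalkine) fell 1.24-fold (adjusted p = 6.09e-05 in the set test). With an estimated correlation the cytokine list had an adjusted p of 0.128. T and NK cell markers rose in 10 of 14 members, with Cd3e (5.14-fold, rounding bounds 0.85 to 4.12 on the log2 scale) and Cd4 (2.01-fold), while Il7r fell 2.05-fold. Their adjusted p was 0.00728, or 0.231 with an estimated correlation. Of 2 measured B cell markers Cd79b rose 1.20-fold, and with so few members the list was not tested as a set. Neutrophil markers did not move as a whole, 1 of 6 being higher and 1 lower (adjusted p = 0.793), and the defensin gene Np4 did not pass (log2 0.13, adjusted p = 0.729). RT1-Da lay in the piled-up range in ligation, and Il7r and Cd79b did not pass under quantile normalization between arrays, nor Cd79b with the probes of a gene averaged. Il18, RT1-DMb, Cd4 and Cd79b each had 2 probes, of which 1 passed the test.

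Markers of glia moved in both directions. Of 12 satellite glia markers 4 rose and 5 fell, with Gfap (glial fibrillary acidic protein) up 7.83-fold (2.97 ± 0.18), Fabp7 down 2.79-fold and Aldoc down 1.86-fold, while Apoe did not pass (log2 0.03, adjusted p = 0.742). The satellite glia list had an adjusted p of 0.963, and its median (-0.20) differed in sign from its mean (0.06) and from the direction of the test. Myelin and Schwann cell markers fell in 8 of 13 members and rose in 3, with the myelin transcription factor gene Egr2 up 2.86-fold (adjusted p = 0.423 for the list). Mag did not pass (log2 0.04, adjusted p = 0.85), and Sox10, a transcription factor of glia, rose 1.36-fold but was lower by 0.06 under quantile normalization between arrays, where it did not pass. Repair Schwann cell genes rose in 4 of 13 members and fell in 2, with Shh up 1.42-fold and Igfbp2 down 1.99-fold, and the list did not pass (adjusted p = 0.3).

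Genes of connective tissue and of dividing cells rose. Fibroblast and matrix genes were higher in 16 of 18 members, with the metalloproteinase inhibitor gene Timp1 up 4.12-fold (2.04 ± 0.04, adjusted p = 1.98e-07), the collagen gene Col5a2 up 3.33-fold and the decorin gene Dcn up 2.63-fold. The list had an adjusted p of 3.29e-06, or 0.268 with an estimated correlation. Cell cycle genes rose in 22 of 24 members, among them the mitotic kinase gene Cdk1 (4.33-fold), Prc1 (3.64-fold) and Cdc20 (2.63-fold), and Kif20a fell 1.14-fold. Their adjusted p was 5.94e-08, or 0.174 with an estimated correlation. Endothelial and pericyte markers rose in 6 of 12 members, with Cdh5 (1.70-fold) and Pecam1 (1.40-fold), while Vwf did not pass (log2 -0.01, adjusted p = 0.939). The endothelial list did not pass (adjusted p = 0.0655), but it passed without ligation replicate 1 and with fry. Dcn lay in the piled-up range in ligation. Kif20a did not pass under quantile normalization between arrays, with the probes of a gene averaged, with the replicate block or on ligation arrays 1 and 4 alone.

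Genes of energy and cholesterol metabolism fell. Oxidative phosphorylation genes fell in 21 of 24 members with 0 higher, by small amounts, as for the complex subunit genes Sdha (1.77-fold) and Ndufs3 (1.67-fold), and their adjusted p was 4.64e-06, or 0.178 with an estimated correlation. Under quantile normalization between arrays the oxidative phosphorylation list did not pass. Ndufs3 had 2 probes, of which 1 passed the test. Cholesterol synthesis genes fell in 17 of 20 members, with Insig1 (2.11-fold), Sqle (squalene epoxidase, 1.96-fold) and Cyp51 (1.91-fold) as examples. The cholesterol list had an adjusted p of 2.87e-04, or 0.345 with an estimated correlation. Immediate-early and heat shock genes rose in 7 of 11 members, with Fos (7.53-fold) and Junb (3.28-fold), whereas the chaperone gene Hsph1 fell 2.33-fold. That list had an adjusted p of 0.0211, or 0.197 with an estimated correlation.

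Lists of markers of neighbouring tissues did not pass the set test or, for erythrocytes, were too short for it. Of 10 skeletal muscle markers, Tnnt3 rose 1.23-fold (adjusted p = 0.0425) and Myh4 fell 1.94-fold (adjusted p = 0.0217), and Myh1 did not pass (log2 -0.03, adjusted p = 0.964). The muscle list did not pass (median log2 change -0.21, adjusted p = 0.611), but under quantile normalization between arrays it was higher in ligation (median 0.82) and passed. Adipocyte markers fell in 2 of 7 members, with lipoprotein lipase, Lpl, down 2.13-fold, and the list did not pass (adjusted p = 0.43). Of 4 erythrocyte markers 0 passed, Hbb having a log2 change of -0.01 (adjusted p = 0.979). Oligodendrocyte and astrocyte markers of the spinal cord fell in 3 of 7 members and rose in 1, with the water channel gene Aqp4 down 2.94-fold (rounding bounds -1.93 to -1.20 on the log2 scale), and the list did not pass (adjusted p = 0.458). Tnnt3 lost its call when any of 7 single arrays was left out and Myh4 without ligation replicate 2 or 3, and both on ligation arrays 1 and 4 alone. Myh4 also lost it with the replicate block, and Myh4 and Aqp4 did not pass under quantile normalization between arrays.

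Of the 30 lists, 28 were tested as sets and 18 passed, 10 higher and 8 lower, and 1 passed with an estimated correlation. Calls were lost also where the estimated correlation lay below the preset 0.01, for sodium channels (-0.033) and for opioid and GABA receptors (-0.025). A call lost with this setting is therefore not by itself a sign that the genes of a list vary together. Besides the endothelial list, some lists that did not pass with camera passed with directional fry. These were calcium channels (adjusted p = 1.2e-04), ionotropic glutamate receptors (2.89e-08), repair Schwann cell genes (2.88e-04), adipocyte markers (0.00253) and the spinal cord markers (0.0448). Fry asks whether the members of a list changed, without comparing them with the other genes as camera does. With 7207 of 10746 genes past the test, passing fry does not set a list apart from other genes. Adjusted over the list alone, the counts of members past the test equalled those above except in 5 lists: large neuron genes 1 higher and 9 lower, opioid and GABA receptors 2 and 13, cell cycle genes 22 and 2, cholesterol synthesis genes 1 and 17, and skeletal muscle markers 0 and 0.

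**Figure D3:**
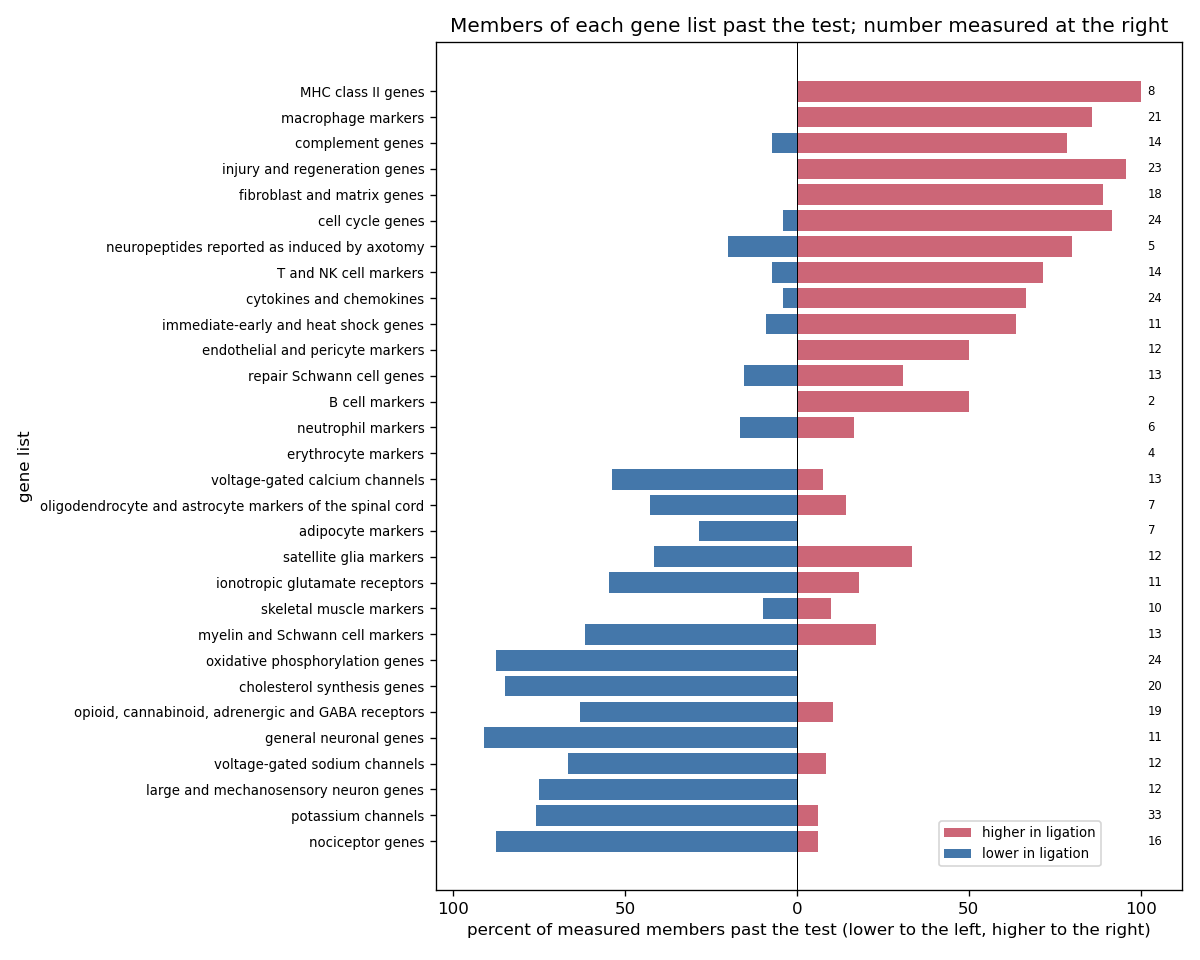
Percent of the measured members of each of the 30 gene lists (vertical axis) that passed the test, higher in ligation to the right in red and lower to the left in blue (horizontal axis), with the number of measured members at the right margin. MHC class II genes reach 100% higher, with 8 of 8, and nociceptor genes have 14 of 16 lower.

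The control arrays were compared with the pooled reference as background, since both carried control material by their labels. Skeletal muscle transcripts were far lower in the control samples than in the reference: Myh1 had a mean log2 ratio of -4.48 ± 0.60 (SD, n = 4, adjusted p = 2.86e-04), Myh4 of -4.30 ± 0.49 and Tnnt3 of -2.98 ± 0.18. The median over the 10 muscle markers was -2.78. In the ligation samples Myh1 lay at -4.51 ± 0.43 and Tnnt3 at -2.68 ± 0.14, so muscle signal was low against the reference in both groups. Csrp3 also lay below the reference in control (-3.99 ± 0.47) and above it in ligation (4.35 ± 0.30). In all, 148 probes differed between control and reference, 33 higher and 115 lower, of which 45 were at least 2-fold lower and 0 at least 2-fold higher. In the same limma fit, 3225 probes had an unadjusted p under 0.05. The count of 148 was 79 without control replicate 1, 72 without control replicate 3, 505 with array weights and 3404 under quantile normalization, which gives all arrays 1 spread of ratios.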

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

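The tests of the muscle and injury-induced signal in the reference, except that of a single share, were chosen after the result was seen, and so were those of bleed, of compression and of the shares in neuronal lists. The splits of the arrays, the single share and the added background were tested as written before. Bootstrap intervals in this part were drawn by resampling genes, so they hold no variation between arrays. They describe the genes named, on these arrays.

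Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many probes past the test as ligation against control, the real one, with 13105 probes against 1 in the highest other split. For probes with at least a 2-fold difference the real split, 1 of 35, gave 1809 and the highest other 1. For both counts the real split stood alone, and 1 of 35 is the smallest share that these splits can give. Every other split mixed ligation and control arrays within its groups, which widened the spread there. The gap in counts is therefore no measure of chance. For the number of gene lists the splits do not exclude chance, as 5 of the 35 splits gave at least 18 lists and the highest other gave 20. The other splits with as many exchange 1 array and so keep part of the real contrast: the 16 of that kind gave 13 to 20 lists, and the 18 that exchange 2 gave 1 to 5.

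Skeletal muscle transcripts were higher in the pooled reference than in the samples of either group. A reference made of the 4 control samples alone is argued against, since 10 of 10 muscle markers had a mean reference intensity on the control arrays above the highest control sample, with Myh1 at 3.07 against 0.23. Dye bias unrelated to what the genes do is argued against too: 0 of 10000 random lists matched on intensity had a median control ratio as low as -2.78. Muscle RNA in the tissue the reference was made from is not decided: of 20 further muscle genes 7 lay more than 0.5 below the reference in both groups (15.4% to 59.2%, an interval added after the count was seen), fewer than the 3 in 4 expected, yet their median in control was -0.33, with 0 of 10000 random lists as low. No group of the design differs in this, so no biological explanation was tested.

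Injury-induced transcripts were higher in the reference than in the control samples: over the 40 genes that rose at least 8-fold, the median log2 excess on the control arrays was 0.38 (95% bootstrap interval 0.31 to 0.46). Bleed of the Cy5 signal of ligation samples into Cy3 is argued against, since no ligation sample was on those arrays. With the genes chosen on 2 control arrays and measured on the other 2, the medians were -0.38 and -0.44, and 0 of 10000 random lists matched on intensity were as low in either case, which argues against dye bias unrelated to what the genes do. RNA of ligated-like ganglia in the reference at one share stays open as a hypothesis: the implied share had a median of 2.93%, and its upper quartile was 1.82 times the lower (1.48 to 2.62), although 3 of the 40 genes had an implied share below 0. The labels call the reference a control pool and the design gives no groups that differ in it, so no biological explanation was tested.

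Falls were shallower on ligation arrays 2 and 3 than on arrays 1 and 4 in 96.7% of the 91 genes that fell at least 4-fold, with a median gap of 0.42 on the log2 scale. The intervals below are over genes, and the spread between arrays does not enter them. A constant background added to the sample channel is argued against, as the gap was larger by 0.25 (0.02 to 0.63) in the 30 brightest of them than in the 31 dimmest, and so is bleed of the reference signal into Cy5, as the muscle markers gained 0.24% of the reference (-1.13 to 1.55) against a lower quartile of 5.79% in the 19 genes that fell at least 8-fold. Compression alike in both directions is argued against because the falls on arrays 2 and 3 were 0.813 times those on arrays 1 and 4, while the rises of 177 genes were 1.04 times. Unligated-like RNA left in the samples would bring the transcripts of all neurons, yet its implied share was -8.49% (-24.1 to -2.47) in 18 fallen members of the large neuron and general neuronal lists, against 7.54% in the 19 genes, whose upper quartile of the difference between arrays was 1.60 times the lower. The 14 fallen nociceptor genes, which overlap with the 19, gave 9.42% (7.48 to 14.9), with 2 of them below 0, P2rx3 (-6.06%) among them; the design names no difference between the samples, so no biological explanation was tested.

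Among 286 groups of 4 arrays tested with Dixon's test, over the genes, lists and array measures of the text, 29 (10.1%) held 1 array far from the other 3. Chance gives about 1 in 20 where values are continuous. In 16 of the 29 the other 3 arrays were equal, among them some list medians and the median sample intensity of ligation replicate 2. With 3 equal values any differing value counts as far, so the rate of 1 in 20 does not apply to these 16. Rounding can make values of dim probes equal, but its part in these groups was not tested. Over all 137 genes of the naming rule and the 15 others, 46 of 366 groups held such an array.

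In log2 ratios, control replicate 1 lay apart for Cck (-0.14), Shh (-0.13), Cd79b (0.11), cytokines and chemokines (median -0.11) and repair Schwann cell genes (0.022). Control replicate 2 lay apart for Gfap (-0.80, the others -0.10 to 0), Pecam1 (-0.15) and the opioid, cannabinoid, adrenergic and GABA receptors (0.043). Control replicate 3 lay apart for Cldn4 (-1.585), Il24 (-1.0) and Kcnmb4 (-0.18). Control replicate 4 lay apart for Sprr1a (-0.26), Adcyap1 (0.23), Prc1 (-0.029), Gfra3 (0.24), Kcnn1 (0.15), Gabrb1 (0.41), Grik2 (-0.47), Il7r (0.56), Mmp12 (0.16) and potassium channels (0.021). Ligation replicate 1 lay apart for Pecam1 (0.22) and Hsph1 (-1.08). Ligation replicate 2 lay apart for Tnnt3 (-2.48) and in its median sample intensity (0.22 against 0.21). Ligation replicate 3 lay apart for Gabbr2 (-1.70) and the opioid, cannabinoid, adrenergic and GABA receptors (-0.51). Ligation replicate 4 lay apart for Oprm1 (-1.585) and for large and mechanosensory neuron genes (median -1.04, the others -1.25 to -1.23).

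The authors' p-values, used in no comparison, were under 0.01 for at least 20.7% of spots on a ligation array and for 0.7% to 1.2% on the control arrays.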

How the results depend on the processing

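Rounding noise and ligation arrays 1 and 4 alone were tried after seeing the data. Quantile normalization gave 6365 probes past the test, 1012 at least 2-fold and 3404 for control against reference (1722 higher and 1682 lower, an even division in place of 33 and 115); by construction it gives all arrays 1 spread of ratios. It turned Sox10 (-0.059), Ckm (0.75) and the muscle list (median 0.82). Fewer probes were tested above the median intensity (8559 and 1102 probes) and with genes as the unit (7207 and 1201 genes). Array weights gave 505 for control against reference, and averaging probes turned Ccna2 to 0.66; the cause was not tested. With an estimated correlation 1 list passed, the potassium channels. With fry 24 lists passed as directional and 26 as mixed. Leaving out 1 array gave 12019 to 12730 probes, 1734 to 1861 at least 2-fold, 17 to 19 lists and 72 to 176 for control against reference, where control replicates 1 (79) and 3 (72) moved the count most.

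The numbers do not pair the samples by the labels; ligation and control arrays of 1 number correlated at 0.106, 0.074, 0.136 and 0.161, each array best with its own number, a hint from the data and not the design. With the replicate block 12583 probes and 17 lists passed, the neuropeptides not (adjusted p = 0.0625). Welch's test per probe gave 11761, the sample channel alone 9999, eBayes with trend and robust 13089, rounding noise 12317 (91.2% of calls kept, 71.4% in the dimmest 25% of probes) and ligation arrays 1 and 4 alone 11309. Of the values of single genes under other settings, 1268 kept direction and side of the threshold, 34 lost the call, 12 gained it and 3 reversed; with 1 array left out, 1179 kept both, 32 lost the call and 5 gained it. Median centring moved nothing, since medians were already 0. The deposited log10 table, a rounded copy, was not run. Dim signals limit the rest: rounding steps were coarse where intensities were under 0.1.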

Other observations

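All tests in this part were chosen after seeing the data. Genes were grouped by the letters that open their symbols, with Rps6k kinases, a binding protein and a pseudogene kept out of the ribosomal families, and the 115 families with at least 10 measured members were tested with camera. Genes of the small subunit of the cytosolic ribosome, with symbols that open with Rps, rose in 22 of 23 members (median log2 change 0.71, adjusted p = 1.18e-08), and those of the large subunit, Rpl, rose in 29 of 33 and fell in 2 (median 0.65, adjusted p = 1.84e-08). With an estimated correlation the adjusted p was 0.556 for each. Under quantile normalization between arrays the medians were 0.66 and 0.57. Matrix metalloproteinase genes, Mmp, rose in 11 of 15 members (adjusted p = 0.0204, or 0.556 with an estimated correlation), with the stromelysin gene Mmp3 up by 4.00 ± 0.17 (SE) on the log2 scale and the macrophage elastase gene Mmp12 up 12.5-fold (3.64 ± 0.33) on a dim probe. Collagen genes, Col, rose in 17 of 23 (adjusted p = 0.00296, or 0.661 with an estimated correlation), and genes of splicing factors, Srsf, in 8 of 10 (adjusted p = 0.0233, or 0.556).

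Genes of the mitochondrial ribosome fell while those of the cytosolic ribosome rose: 29 of 40 Mrpl genes (median -0.31, adjusted p = 0.00139) and 16 of 23 Mrps genes (median -0.22, adjusted p = 0.0181) were lower. All 10 Ndufa and all 10 Ndufb genes, subunits of respiratory complex I, fell, with medians of -0.47 and -0.43. So did 11 of 13 Timm genes of mitochondrial protein import (median -0.34). With an estimated correlation the adjusted p was 0.556 for each of these 5 families. Under quantile normalization between arrays these mitochondrial families did not pass, with medians of 0.01 for Mrpl, -0.03 for Mrps, -0.05 for Ndufa, -0.03 for Ndufb and -0.03 for Timm. Since that setting enlarges small control ratios, these losses alone do not show that the falls were absent. Of the 115 families 13 passed, and 0 with an estimated correlation.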
